A study of Polistes fuscatus with 17 samples.

How the data were processed

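RNA was measured in 17 single adult brains of the paper wasp Polistes fuscatus, 1 library per wasp. Per the labels' protocols, wasps were trained in a T-shaped maze for 40 trials, were killed by freezing 30 minutes after the last trial, and total RNA of each brain was extracted with an RNeasy kit and made into a TruSeq library. The 4 groups came from the library titles: 5 foundresses trained to faces, 4 foundresses trained to patterns, 4 workers from a non-natal nest of their own species and 4 workers from a nest of another species, P. metricus, the workers all trained to faces. The titles call both worker groups a nest swap, so the nest groups go by the species of that nest and not by the nest of origin. Each wasp is a separate animal, and the nest or colony in which it hatched is not given in the labels.

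The deposited table holds whole-number counts of reads for 157691 contigs of a transcriptome assembly, not normalized by the authors as far as the values show. The submitters' processing notes name Trimmomatic 0.32, Bowtie2 and eXpress without saying what each did. The aligner settings, the versions of the other tools and the treatment of reads that matched several contigs are not given in the sources used here. Contigs with neighbouring identifiers often moved together, and reads shared between such contigs cannot be parted from the counts, so numbers of contigs are not numbers of genes. The files do not pair the contig identifiers with gene names: 0 of the identifiers occur among the 13634 entries of the gene table of assembly CU_Pfus_HIC. Gene lists chosen before the data were examined were therefore not tested, and contigs are given by identifier.

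Counts were analysed in R 4.3.3 with edgeR 4.0.16. Contigs were kept by edgeR's expression filter applied by group, which left 61002 contigs holding 99.4% of all counts and removed 96689, of which 2245 had 0 counts in every library. Libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 17 libraries together, and contrasts were tested by edgeR's quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over all tested contigs at a false discovery rate (FDR) of 0.05. The model had 13 residual degrees of freedom, and the common dispersion gave a biological coefficient of variation of 0.251. CPM values are counts scaled to library size on the TMM scale, log2 CPM used a prior count of 2, and the standard error (SE) of a log2 fold change was taken as its size over the square root of F.

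The contrasts were foundresses trained to faces minus those trained to patterns, workers from conspecific nests minus those from allospecific nests, and foundresses trained to faces minus the mean of both worker groups. The overlap of the first 2 contrasts was set against the number independent lists give. For each contrast the contigs named were fixed before the data were examined: the 2 higher and the 2 lower with the smallest p among those past the FDR whose groups did not overlap in CPM, or, with none past it, the same number with the smallest p, said not to pass. Contigs named outside that rule are said to be. Values per library were compared by exact permutation tests, two-sided, with adjustment over the 12 tests made. No pair of libraries in a group was as close as sampling noise, the lowest chi-square per degree of freedom being 6.69.

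Total counts ranged from 7.69 to 20.4 M per library. The procedure was tested on simulated data, in which 200 contigs with a mean count of at least 20 were changed among counts drawn with the measured means, library sizes and dispersions. For faces against patterns it recovered 10.4% of contigs changed 1.5-fold, 44.8% of those changed 2-fold and 92.4% of those changed 4-fold. For the nest contrast recovery was 0%, 29.9% and 95.5% at these sizes, and for foundresses against workers it was 10.4%, 58.2% and 100%. False calls made up 1.01%, 6.74% and 5.08% of the calls in these contrasts. Each contig was drawn independently with 1 mean over all wasps, and no library was given a wider spread of its own. At an unadjusted p under 0.05 the simulated nest contrast had 4.72% of unchanged contigs, while the measured one had 2.65% of all contigs. The rates may therefore differ in the measured data.

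Alternatives chosen before the data were examined were DESeq2 size factors, DESeq2 1.42.0 with its Wald test, limma-voom (limma 3.58.1), no filter, a filter of 1 CPM in 4 libraries, only the libraries compared, collection month as a covariate, 1 month only, 1 worker group only, FDR levels of 0.1 and 0.01, and leaving out each wasp in turn. Added after the data were seen were leaving out F17, F17 with F3, or FW28 with F55, library quality weights, robust dispersions, 1 contig per run of neighbouring identifiers, leaving out a set of abundant contigs, and scaling by library totals alone. A test of distances between groups, a look-up of contigs in separate libraries and an index placing each wasp between the castes were also added then, as was the share of contigs at which a wasp, held out of their choice, lay on the side of either caste. Summing contigs by a shared gene was planned and not run, because the identifiers show none. Figures were drawn with matplotlib 3.10.9.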

Results

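The series asked how brain gene expression goes with learning of faces in P. fuscatus, a paper wasp whose foundresses tell nest mates apart by their facial markings. Foundresses are mated females that start nests in spring, and workers are their daughters that emerge in summer. Total counts averaged 17.3 ± 2.21 M (SD, n = 5) in foundresses trained to faces, 13.4 ± 3.84 M (n = 4) in those trained to patterns, 18.6 ± 1.60 M (n = 4) in workers from conspecific nests and 18.8 ± 1.65 M (n = 4) in workers from allospecific nests. Wasp F3, trained to patterns, had the lowest total, 7.69 M, and F29, trained to faces, the highest, 20.4 M. All foundresses trained to faces were collected in May, those trained to patterns in May and June, and the workers in July and August.

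1 of the 17 brains stood apart from the rest in its contig profile. Wasp F17, a foundress trained to patterns, had a median correlation of 0.872 with its group, across contigs, against 0.942 for the other members. Its log2 CPM deviated from the median of the other libraries with a median absolute deviation (MAD) of 1.03, against 0.278 to 0.421 in the other libraries. The first principal component held 30.02% of the variance, and F17 lay at its far end. The number of contigs detected at an equal depth of 7694420 counts was 84116 ± 1187 in foundresses trained to faces and 82018 ± 1392 in workers (n = 8), a difference that missed the threshold after adjustment (exact permutation test, p = 0.0256, adjusted p = 0.154 over 12 tests).

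**Figure D1:**
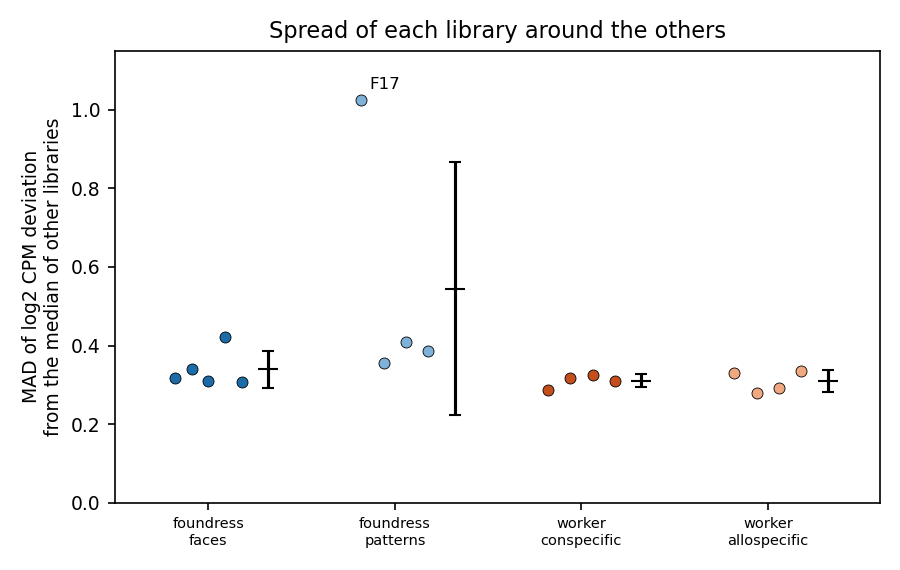
Spread of each library, as the MAD of its log2 CPM deviation from the median of the other libraries, by group, with points for wasps and bars for the mean ± SD. F17 lies at 1.03 and the other libraries between 0.278 and 0.421.

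Foundresses trained to faces and those trained to patterns did not differ in any contig past the FDR. Of the 61002 contigs, 0 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where the lowest adjusted p was 0.676. At an unadjusted p under 0.05 there were 4356 contigs, 7.14% of those tested, a count that was 7217 without F17, 7262 without F34, 3577 to 3704 without F29, F35, F42 or F55 and 9599 with month as a covariate. It was 2030 of 57507 with only the libraries compared, which is under 5%, and 10425 of 63779 with May wasps only. Both the month and the May settings set the foundresses trained to faces against F17 and F3 alone, so they are not separate results. F17 was the widest library and F3 the one of lowest total. The groups did not overlap in 838 contigs, 1.37%, where chance gives 1.59%. The contigs with the smallest p, none of which passed, were PfusTSAr1.0-034626, at 5.07 ± 0.443 CPM (n = 5) with faces and 2.91 ± 0.524 CPM (n = 4) with patterns, and PfusTSAr1.0-107898, at 1.42 ± 0.685 and 0.361 ± 0.216 CPM, on the higher side. On the lower side were PfusTSAr1.0-030869, at 0.230 ± 0.145 and 2.06 ± 1.72 CPM, and PfusTSAr1.0-084612, at 8.89 ± 1.20 and 13.9 ± 1.65 CPM. Their log2 fold changes were 0.82 (SE 0.16), 2.01 (SE 0.42), -3.12 (SE 0.63) and -0.64 (SE 0.13), each with an adjusted p of 0.676 in edgeR. DESeq2 called 11 contigs, 10 higher and 1 lower, keeping an adjusted p for only 3044, while limma-voom called 0. With the low-count filter off, edgeR called 5, all lower with faces, among them PfusTSAr1.0-030869 (adjusted p = 0.0379, against 0.0379 to 0.841 over its alternatives), and without F52 it called 1.

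Workers from nests of another species differed from workers from conspecific nests in 7 of 61002 contigs, 2 higher and 5 lower in the conspecific group. PfusTSAr1.0-048649 stood at 29.4 ± 6.83 CPM (n = 4) in the conspecific group and 91.5 ± 3.18 CPM (n = 4) in the allospecific group, and in foundresses it was 22.9 ± 4.23 CPM with faces and 27.7 ± 9.21 CPM with patterns. PfusTSAr1.0-113615 was also lower in the conspecific group, at 0.295 ± 0.111 against 1.52 ± 0.146 CPM, a level of few counts. PfusTSAr1.0-029153 and PfusTSAr1.0-102313 were higher there, at 18.1 ± 19.2 against 0.491 ± 0.0933 CPM and 9.70 ± 3.93 against 0.423 ± 0.172 CPM. Levels of PfusTSAr1.0-029153 ran from 0.916 to 45.7 CPM among the conspecific workers and were 0.0392 ± 0.0626 CPM in foundresses trained to faces. PfusTSAr1.0-102313 stood at 4.86 ± 3.23 CPM in foundresses trained to faces, with F25 at only 0.144 CPM, and at 4.11 ± 1.68 CPM in those trained to patterns.

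The log2 fold changes of the nest contrast were -1.64 (SE 0.21, adjusted p = 0.0188) for PfusTSAr1.0-048649 and -2.33 (SE 0.33, adjusted p = 0.0348) for PfusTSAr1.0-113615 in edgeR. They were 5.18 (SE 0.76, adjusted p = 0.0348) for PfusTSAr1.0-029153 and 4.51 (SE 0.68, adjusted p = 0.0391) for PfusTSAr1.0-102313. The remaining 3 contigs, named after their values were seen, were PfusTSAr1.0-094469, PfusTSAr1.0-094470 and PfusTSAr1.0-094476, whose identifiers lie close together. Their log2 fold changes were -0.76, -0.74 and -0.80 (SE 0.12, 0.11 and 0.12), and in edgeR their adjusted p were 0.0462, 0.0434 and 0.0348. In all 7 contigs the 4 wasps of one group lay on 1 side of the 4 of the other. Over all contigs 1897, 3.11%, had groups that did not overlap, where chance gives 2.86%.

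Counts of nest calls depended on which wasp was left out, with 0 to 5 without 1 of the workers and, although foundresses do not enter the contrast, 1 without F29, F35, F42 or F55, 2 without F3, 3 without F34 and 16 without F17, while the log2 fold change of PfusTSAr1.0-048649 ran from -1.82 to -1.58 over its alternatives. With month as a covariate 2 contigs passed, with July wasps only 0, DESeq2 called 36, and limma-voom called 6, all lower, with adjusted p of 1.00 for PfusTSAr1.0-029153 and 0.962 for PfusTSAr1.0-102313.

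**Figure D2:**
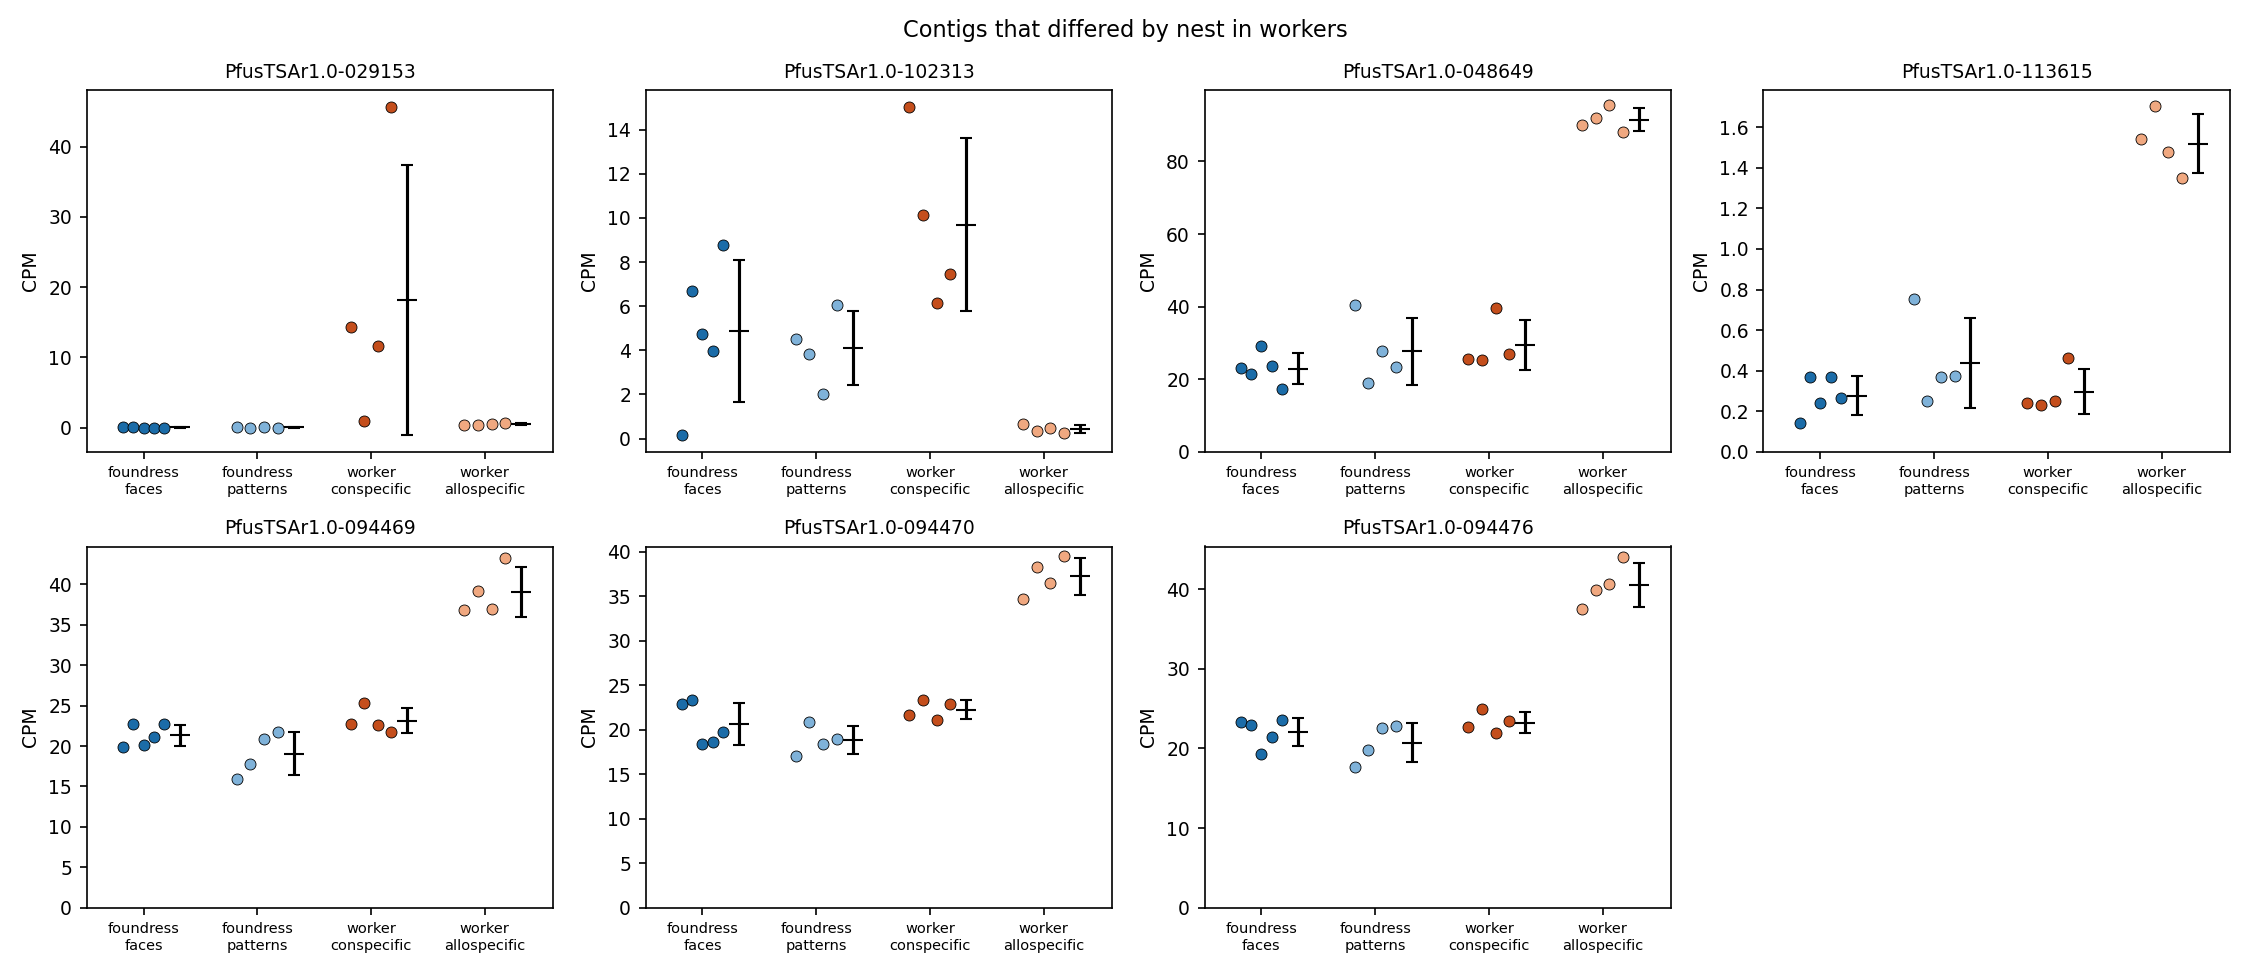
CPM of the 7 contigs past the FDR in the nest contrast, per wasp and group, with bars for the mean ± SD. The 4 allospecific workers lie above all other wasps in the contigs that were lower in conspecific workers, such as PfusTSAr1.0-048649 at 91.5 CPM.

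Foundresses and workers, all trained to faces, differed in 1493 of 61002 contigs, 856 higher and 637 lower in foundresses. Contigs higher in foundresses had a median log2 fold change of 1.06 and 470 of them differed over 2-fold, while those lower had a median of -0.79 and 207 over 2-fold. By mean abundance, a division chosen after the data were seen, the contigs called higher in foundresses were 1.89% of those tested under 2 CPM, 1.16% from 2 to 8, 1.16% from 8 to 32, 1.32% from 32 to 128 and 2.17% over 128 CPM. Those called lower rose over the same steps, from 0.433% to 0.870%, 1.29%, 2.36% and 5.42%. PfusTSAr1.0-084830 stood at 2.72 ± 0.410 CPM (n = 5) in foundresses and 0.563 ± 0.228 CPM (n = 8) in workers, and PfusTSAr1.0-098484 at 4.79 ± 1.79 and 0.979 ± 0.413 CPM. PfusTSAr1.0-109506 and PfusTSAr1.0-109516 were lower in foundresses, at 77.7 CPM (60.1 to 94.7) against 190.3 ± 13.4 CPM and 83.6 ± 14.6 against 205.0 ± 16.4 CPM.

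Foundresses trained to patterns, which did not enter this contrast, had levels on the side of the other foundresses in these 4 contigs, at 2.70 ± 0.538, 3.95 ± 1.66, 85.8 ± 4.96 and 95.9 ± 8.91 CPM (n = 4). The log2 fold changes of foundresses over workers were 2.26 (SE 0.23, adjusted p = 0.000143) for PfusTSAr1.0-084830 and 2.34 (SE 0.28, adjusted p = 0.000346) for PfusTSAr1.0-098484 in edgeR's quasi-likelihood test. They were -1.29 (SE 0.11, adjusted p = 4.7e-05) for PfusTSAr1.0-109506 and -1.29 (SE 0.12, adjusted p = 5.1e-05) for PfusTSAr1.0-109516. All 5 foundresses lay on 1 side of all 8 workers in 785 of the called contigs, and in 2135, 3.50%, of all contigs, where chance gives 0.155%. At an unadjusted p under 0.05 there were 10531 contigs, 17.3% of those tested.

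Caste, collection season, age and rearing on a non-natal nest differ together here, so the contrast describes these groups and parts none of them. The month covariate had terms for June and August only. It left May foundresses against July workers, so it cannot adjust this contrast for their season. Leaving out any face-trained wasp except F25 or F55 moved the count of calls by over 1.5 times, to between 394 without F42 and 909 without FW11, or to 2341 without FW28, and the count was 6121 with F17 left out, 6147 with only the libraries compared, 445 with month as a covariate, 3232 with DESeq2, 181 against conspecific workers (59 higher, 122 lower) and 812 against allospecific workers (356 higher, 456 lower).

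**Figure D3:**
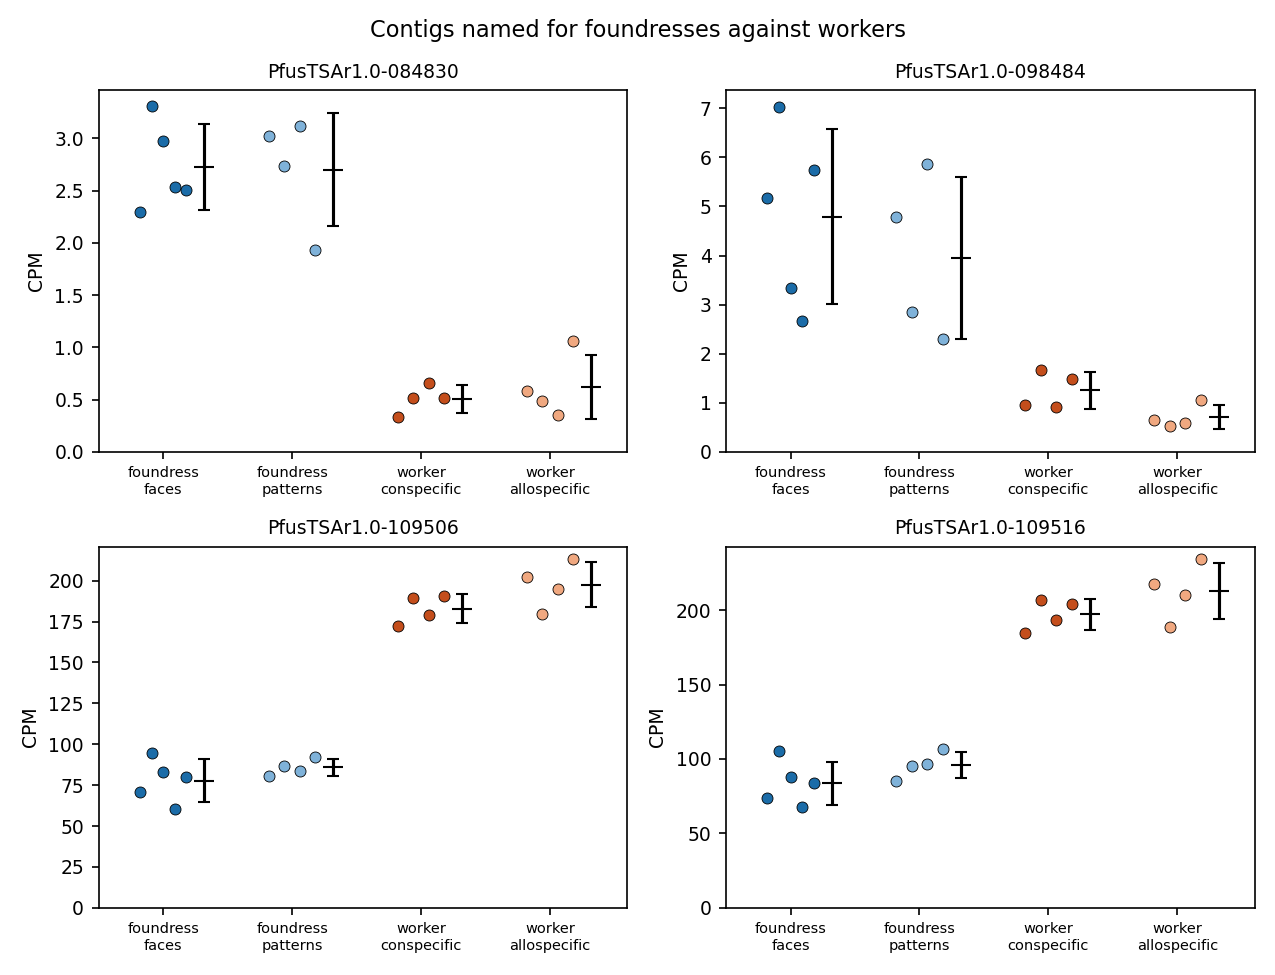
CPM of the 4 contigs named for foundresses against workers, per wasp and group, with bars for the mean ± SD. In PfusTSAr1.0-109506 the foundresses trained to faces lie between 60.1 and 94.7 CPM and the workers between 172.3 and 213.3 CPM.

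The training and nest contrasts shared 0 contigs past the FDR in edgeR, with 0 and 7 called. At an unadjusted p under 0.05 in both, 192 contigs were shared, 68 in the same direction and 124 in opposite directions, where independent lists give 55.7 and 59.6. Across contigs, which are not independent replicates, the log2 fold changes had a Pearson correlation of -0.0791 and a covariance of -0.00945. Among 100 draws of wasps relabelled within foundresses and within workers, the real one included, 55 gave a correlation at least as far from 0, and they ran from -0.295 to 0.407.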

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

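The tests of F17, of 1 locus behind the abundant contigs and of leaving F17 out of the shared fit were chosen after the result was seen, as were the abundant set itself, the index between castes, the test at contigs that part the castes and the scaling by totals. By Dixon's test, 7 of 84 sets of values held a wasp far from its group, where chance gives about 4.2. Wasp F3 had a total of 7.69 M against 14.9 to 15.8 M in the other foundresses trained to patterns, and F42 had a MAD of 0.421 against 0.308 to 0.339 in the other foundresses trained to faces. In conspecific workers, FW28 had 39.5 CPM of PfusTSAr1.0-048649 against 25.4 to 27.0 CPM, and FW47 had 0.461 CPM of PfusTSAr1.0-113615 against 0.229 to 0.252 CPM. Both contigs were still lower in these wasps than in each allospecific worker.

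Wasp F17 stood out in its correlation with its group, 0.872 against 0.942, and in its MAD, 1.03 against 0.356 to 0.410. Its MAD was also 0.882 over 2590 abundant contigs, where the other libraries had 0.193 to 0.312. Low depth is argued against by F3, which had the lowest total and a MAD of 0.356, and a few abundant contigs by F34, which had the highest share of counts in its top 10 contigs and a MAD of 0.410. Noise of single contigs, independent of their neighbours, is argued against by the correlation of deviations between neighbouring contigs, 0.398 in F17 and 0.201 to 0.340 in the others. Noise in reads that neighbours share would move them together too, so it stays open. At equal depth F17 had 78448 contigs detected, the fewest of all libraries, against 86876 to 92188 in the others of its group. Of the tested contigs, 2859 were over 4-fold lower in F17 than the median of the other libraries and 798 over 4-fold higher. Among the abundant contigs the larger part went up, with 16.2% over 2-fold higher and 11.4% over 2-fold lower. RNA quality and dissection stay open, and no biological explanation was tested.

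Wasp FW28 held 5.57% of its counts in a set of 15 abundant contigs that vary together, against 0.849 to 1.499% in the other conspecific workers, and F55 had the lowest share of the foundresses trained to faces, 1.54%. The 15 contigs form 7 separate runs of identifiers, so they are not 1 block of neighbouring contigs. Their sequences were not compared and distant contigs may share reads, so 1 locus counted many times stays open. An index was taken over 2655 contigs called without FW28 and F55, with workers at 0 and foundresses trained to faces at 1. On it FW28 lay at 0.552 and F55 at 0.439, between the other workers, at -0.0209 to 0.110, and the other foundresses trained to faces, at 0.787 to 1.25 (with each wasp held out of the choice of its own contigs 0.513 and 0.487, against -0.00960 to 0.160 and 0.606 to 1.05, where both lie within the SD of 0.186 of the lowest foundress). Both meet the bound of 0.5 for a wrong label that was set before the index was computed, FW28 by 0.0520 and F55 by 0.0611, but after the values were seen the bound was widened by both spreads, of which these exceed that of the workers, 0.0472, and not that of the foundresses, 0.195, because neither wasp lay within the range of the other caste. At 186 contigs that part the other wasps of the castes by over 0.5 log2, F55 lay on the worker side at 52.7%, against 88.5 to 95.5% in other workers held out (SD 2.88), which argues against a wrong label, although it lay on the foundress side at 47.3%, against 70.2 to 95.5% in other foundresses (SD 8.38). FW28 lay on the foundress side at 67.7%, within that SD of the lowest foundress, so for FW28 a wrong label cannot be told apart from a wasp between the castes, and a mixed library was not tested for either.

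Library composition stays open as a source of the 1493 calls between foundresses and workers. An equal shift of all contigs of a library cannot alone give calls on both sides, and these were 856 higher and 637 lower in foundresses. TMM centres the changes, with a median of 0.00454 log2 over all contigs, so calls on both sides were likely beforehand. A bias that varies with abundance was not tested: 81.3% of calls were higher in foundresses under 2 CPM and 28.6% over 128 CPM. With libraries scaled by totals alone 49.0% of 1260 calls lay on the smaller side, 618 being higher and 642 lower. The scaling factors this leaves out differed by -0.0760 log2 between foundresses and workers, where called contigs had a median change of 0.930 log2. That is too little to put nearly all calls on 1 side, so it adds no test. The 1519 calls with the abundant set left out say nothing, because no library size moved by over 0.0138 log2. The widest library may lower the count, since 6121 passed with F17 left out of the shared fit, the main 1493 all among them. Of 100 splits of the 13 face-trained wasps, the real one included and out of 1287 possible, 2 gave as many calls. This argues against chance as the whole source of the count, but it was not adjusted over the tests of splits made. The other of these 2 splits gave 1953 calls, with FW28 in place of F55, which points to the structure in the paragraph on those wasps. Season, age, rearing and caste stay open as untested.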

How the results depend on the processing

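The settings that leave out F17, F17 with F3, FW28 with F55 or the abundant set, that use library quality weights, robust dispersions or 1 contig per run, and all those of the library spread, distance, abundant set, disjoint library, caste side and scaling by totals tests were chosen after the data were seen. No paired analysis was possible because each wasp is a separate animal and the labels record no pairs. No direction reversed in the named contigs. The 4 named for foundresses against workers passed the FDR in all 116 alternative values, with log2 fold changes of 2.10 to 2.46, 1.94 to 2.74, -1.36 to -1.21 and -1.38 to -1.22. In the nest contrast 78 of 153 values missed the FDR, and in the training contrast 1 of 87 passed it. 

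Between foundresses and workers the calls were 3205 at FDR 0.1, 246 at FDR 0.01 (98 higher, 148 lower), 445 with month as a covariate (146 higher, 299 lower), 6147 with only the libraries compared, 181 with conspecific (59 higher, 122 lower) and 812 with allospecific workers only (356 higher, 456 lower), 3232 with DESeq2, 8425 with quality weights, 6121 without F17 and 2734 without FW28 and F55 (2036 higher, 698 lower). Leaving out each face-trained wasp gave 394 to 2341, and the fit with month cannot part season from caste here. For the nest contrast they were 0 at FDR 0.01, 49 with no filter, 2 with month as a covariate, 28 with only the libraries compared, 0 with July only, 34 with quality weights, 16 without F17 and 36 with DESeq2, 6 with limma-voom (0 higher), and 0 to 5 leaving out each worker. For faces against patterns they were 5 with no filter, 11 with DESeq2 and 0 to 1 leaving out each foundress. Contigs shared by the training and nest contrasts were 192 at an unadjusted p under 0.05. FW28 lay on the foundress side at 70.0% of the 20 contigs that part the castes by 1 log2. That is within the 57.7 to 100% of the other foundresses, so at this gap FW28 meets the bound for a wrong label. The correlation of F17 with its group was 0.946 with no filter. The cause was not tested for these, except that fewer wasps, contigs or a stricter FDR are part of the settings that name them. Depth limits contigs of few counts, such as PfusTSAr1.0-113615, and summing by gene and gene list tests were not run.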

Other observations

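The abundant set, the look-up in separate libraries, the distance test, the runs of identifiers and the contigs present in some wasps and absent in others were tests chosen after the data were seen. The 15 abundant contigs held 6.56 ± 3.32% of counts in foundresses trained to faces (SD, n = 5), 8.17 ± 5.18% in those trained to patterns (n = 4) and 2.11 ± 1.48% in workers (n = 8). Foundresses trained to faces exceeded workers by 4.46 percentage points (exact permutation test, p = 0.00932, adjusted p = 0.0280 over 3 comparisons), and without FW28 the workers averaged 1.61 ± 0.504% (n = 7). Their log2 fold changes ran from 1.16 to 2.49, and 1 of the 15 passed the FDR in edgeR, 10 of 15 with F17 left out. The set was found on these libraries, so its difference is a hypothesis to test on others, and with other search settings it held 7, 11 or 17 contigs and the difference was 2.26, 3.13 or 4.99 points.

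Foundress and worker differences were seen again in libraries that share no wasp, although season differs with caste there too. The contigs were called in the fit to all 17 libraries, so filter, scaling and dispersions were shared with the look-up libraries. The look-up is therefore not an independent repeat. Of 181 contigs called between foundresses trained to faces and conspecific workers, 177 (97.8%) had the same direction between foundresses trained to patterns and allospecific workers, 151 of them at an unadjusted p under 0.05, and 0 had the opposite direction at that level. With the worker groups exchanged, 770 of 812 (94.8%) kept the direction, 591 at that level, and 5 were opposite at it. Over all contigs the direction was shared by 69.1% and 70.4%. Called contigs lay in fewer runs of identifiers than random contigs: 571 for the 856 higher in foundresses, where random draws had a median of 775.5, and 347 for the 637 lower, where it was 592.

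Over all contigs, groups accounted for 10.7% of the variance in distances between foundresses by training (exact permutation test, p = 0.778), 17.3% between workers by nest (p = 0.114) and 21.3% between foundresses and workers trained to faces (p = 0.000777, the smallest the 1287 splits can give). Adjusted over the 3 tests these are 0.778, 0.171 and 0.00233. With F17 left out the first was 15.4% (exact permutation test, p = 0.286), again short of the threshold.

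Chance cannot be excluded for faces against patterns, since 52 of 100 splits of the 9 foundresses gave as many contigs at an unadjusted p under 0.05 as its 4356, the highest other 12376. The count of calls says nothing there, because all 100 splits must give at least 0. The highest other count, 65 calls, came from a split that put together the 5 foundresses with the highest shares of the abundant set, which points to a structure of the samples other than training. For the nest contrast the real split was the only 1 of 35 with any call, 7 against 0 in the highest other. That is the smallest share 35 splits can give, and it was not adjusted over the tests of splits made. It argues against chance for the count of calls alone, and chance is not excluded for the contrast. At an unadjusted p under 0.05 other splits had up to 2593 contigs against its 1615. Month was tested as the source of the fold changes: in a model with month these were at least 0.972 of their size, which argues against it. Of the 7 contigs 5 then missed the FDR (adjusted p = 0.0657 to 0.144 in edgeR), with log2 fold changes and SE close to before, such as -2.31 (SE 0.34) against -2.33 (SE 0.33) for PfusTSAr1.0-113615. In July wasps, which are fewer, 0 passed and the log2 fold changes were -1.60 for PfusTSAr1.0-048649, -2.72 for PfusTSAr1.0-113615, 4.35 for PfusTSAr1.0-029153, 4.40 for PfusTSAr1.0-102313 and -0.74 to -0.69 for the remaining 3. For the opposite directions of the training and nest fold changes, 55 of 100 draws were as far from 0, so chance cannot be excluded there.

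The nest group of the workers is a candidate explanation for contigs that are present in some wasps and nearly absent in others. Of 26 such contigs in the 17 wasps, the nest groups parted 1, PfusTSAr1.0-110957, chosen after its values were seen, which is more than in 33 of the 34 other splits of the workers and past the bound of 95% set before. Chance is not excluded, as 2 of the 35 splits part as many, and the conspecific worker FW25 had only 0.802 CPM of it and foundresses F29 and F42 0.0530 and 0. This rests on 1 contig, and the nest groups did not part the other 25. The training groups parted 0, and whether such contigs follow families of related wasps was not tested because the labels name no colony of origin.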
